A study of Mus musculus with 9 samples.

How the data were processed

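RNA of 4T1 cells was sequenced in 9 libraries, 3 each of cells in medium (PBS), cells with MRC nanoparticles (MRC) and cells with MRC nanoparticles and 660 nm light (MRC+L), per the labels. Total RNA was extracted with Trizol and libraries were made with an Illumina TruSeq RNA kit, per the labels' protocols. The authors deposited 1 table per library with a raw count of read pairs for each of 55416 genes. The deposited counts were made with featureCounts 2.0.1 over exons summed by gene, with paired ends and the Ensembl release 104 annotation of GRCm39, per the file headers. No strand option was given, so counts of genes that overlap on opposite strands are uncertain, and reads with more than 1 place were not counted, so counts of near-identical copies are uncertain. The aligner was not given in the sources used here.

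Gene symbols, biotypes and GC content came from GENCODE M21, an annotation of GRCm38 that was matched by gene ID and not by position. It gave a symbol to 52083 IDs (94.0%), some of them older names such as Ddx58 and Ero1l. A count was seen for 28539 genes in at least 1 library. Library totals were 18998399, 17555226 and 15751878 counts for PBS, 15983374, 17006443 and 20044166 for MRC, and 18429137, 15019765 and 17057074 for MRC+L. A count of 0 leaves room for 3 counts, or 0.150 to 0.200 CPM by library. The spread between replicates, pooled over genes, exceeded counting noise. Whether replicates or depth limited single genes was not tested.

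Tests were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and tables and plots were made in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9. Genes were kept by the edgeR filter with a minimum count of 10 and a minimum total of 15, which left 13439 genes. The quasi-likelihood test of edgeR with TMM factors and 1 mean per group was fitted to all 9 libraries for MRC against PBS, MRC+L against PBS, MRC+L against MRC, and the 3 groups together. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The prior count was 0.125 for fold changes and 2 for log CPM in the plots. The comparison of MRC+L with MRC was also fitted to its 6 libraries alone, where 12955 genes were kept.

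Lists of genes, 34 in number with 917 entries and 875 different genes, were written by hand before the data were examined, as were the groups, the tests, the rule for naming genes and most of the alternatives. They cover pyroptosis, apoptosis, necroptosis, ferroptosis and iron, NRF2 targets, antioxidant enzymes, heat shock chaperones, ATF4 targets, the unfolded protein response, interferon-stimulated genes, MHC class I presentation, NF-kB targets and cytokines, nucleic acid and TLR sensing, and checkpoint genes with natural killer cell ligands. Further lists hold immediate early genes, p53 targets, S phase, G2 and mitosis, replication-dependent histones, cholesterol synthesis, fatty acid synthesis, glycolysis, HIF targets, nuclear-encoded oxidative phosphorylation and mitochondrially encoded genes. The rest are lysosome and autophagy, metal ion response, cytosolic ribosomal proteins, ribosome biogenesis, epithelial markers, mesenchymal genes, leukocyte markers, fibroblast and endothelial markers, and nuclear-retained RNAs. Some genes are in several lists, so calls of lists that share members are not separate results. Lists with at least 5 tested members, 32 of them, were tested with camera of limma at a preset correlation of 0.01, with adjusted p over the lists, and again with a correlation estimated for each list and with fry.

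Genes were named by a rule. It takes, in each comparison, the 10 largest changes in each direction among called protein-coding genes with a proper symbol whose 3 libraries per group did not overlap and whose higher group had a mean of at least 5 CPM. It adds up to 4 members of each list with the smallest adjusted p, and 19 genes fixed in advance, among them Gsdmd, Gsdme, Casp1, Casp4, Hmgb1, Calr and Cd274. Some genes that the rule names are not reported here.

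The tests were run on simulated data with the depth of these libraries and the spread of each group. For MRC against PBS edgeR found 12.5% of genes changed 1.5-fold, 69.6% of those changed 2-fold and 86.6% of those changed 4-fold, with 50 calls among 12961 unchanged genes, which made 30.5% of all calls where few genes were changed. For MRC+L against PBS there were 39 calls among 12990 unchanged genes. For MRC+L against MRC edgeR found 5.48% of genes changed 1.5-fold and 50.0% of those changed 2-fold with all 9 libraries, and 61.0% and 81.6% with 6 libraries, where 11 of 12745 unchanged genes were called. With 1 spread for all groups 6 of 12944 unchanged genes were called for MRC against PBS, so in simulation unequal spread added false calls there. This run was not made for MRC+L against MRC, where the 2 fits also differ in their libraries. Of 3 lists changed 1.5-fold camera called 3, and of 27 lists without a changed gene it called 0. Each gene was drawn independently, so this run cannot show how often camera calls falsely where members of a list move together. In the real libraries the estimated correlation was 0.965 for cytosolic ribosomal proteins in MRC against PBS.

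Alternatives tried were other scalings (RLE, upper quartile, library size only), other filters, DESeq2, limma-voom, a replicate block, fits without each library in turn, fits of the compared groups alone, a stricter threshold of 0.01, a test against a 1.5-fold change, only protein-coding genes, no mitochondrial genes, and removal of a smooth trend of counts with gene length (lowess span 0.3). Replicate numbers did not pair the libraries, since r across genes of same-numbered libraries lay between -0.185 and 0.0385 and of others between -0.126 and 0.204. Raw reads were not analysed here.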

Results

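Gene expression was measured by RNA sequencing in 4T1 cells, a mammary carcinoma line of the BALB/c mouse. The cells were kept for 12 h in medium alone (PBS group), in medium with MRC nanoparticles (MRC group), or in medium with MRC nanoparticles and irradiated at 660 nm for 3 min (MRC+L group). The labels print the irradiance as 180 with the unit mV per square centimetre, and they do not spell out MRC. Each group had 3 libraries, 9 in all. The labels do not say that the libraries came from separate cultures, so every p-value measures only the spread between these samples, which may be technical. The tables hold counts per gene. The total per library lay between 15019765 and 20044166 counts, and 18999 to 20514 genes had at least 1 count in a library. A count of 0 allowed a level of up to 0.150 to 0.200 CPM (3 counts, scaled to the library total), which covers counting error only. Levels are CPM scaled by the trimmed mean of M values (TMM), given as mean ± SD over n = 3 libraries. Fold changes are given on the log2 scale with their standard error (SE), and adjusted p-values come from the quasi-likelihood test of edgeR over 13439 genes unless another test is named.

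The exposed libraries lay apart from the PBS libraries on the first principal component, which held 65.6% of the variance. Scores were -85.3 to -49.4 for PBS, 18.4 to 33.0 for MRC and 35.5 to 43.9 for MRC+L. The biological coefficient of variation was 0.280 within PBS, 0.0807 within MRC and 0.0580 within MRC+L. PBS replicate 2 stood apart: its shortest genes lay 1.14 log2 units higher, relative to its longest, than the mean over all libraries, whereas the other 8 libraries lay between -0.293 and 0.122. Among these the MRC+L libraries, at -0.293 to -0.177, did not overlap the MRC libraries, at -0.136 to 0.0546. Without PBS replicate 2 the coefficient for the remaining 8 was 0.0823, against 0.172 for all 9. MRC replicate 1 had 0.957% of its counts in genes without a symbol in the annotation used, and the other libraries had 0.190% to 0.330%. No pair of replicates agreed within sampling noise, since the chi-square per degree of freedom between replicates lay between 3.84 and 157.

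**Figure D1:**
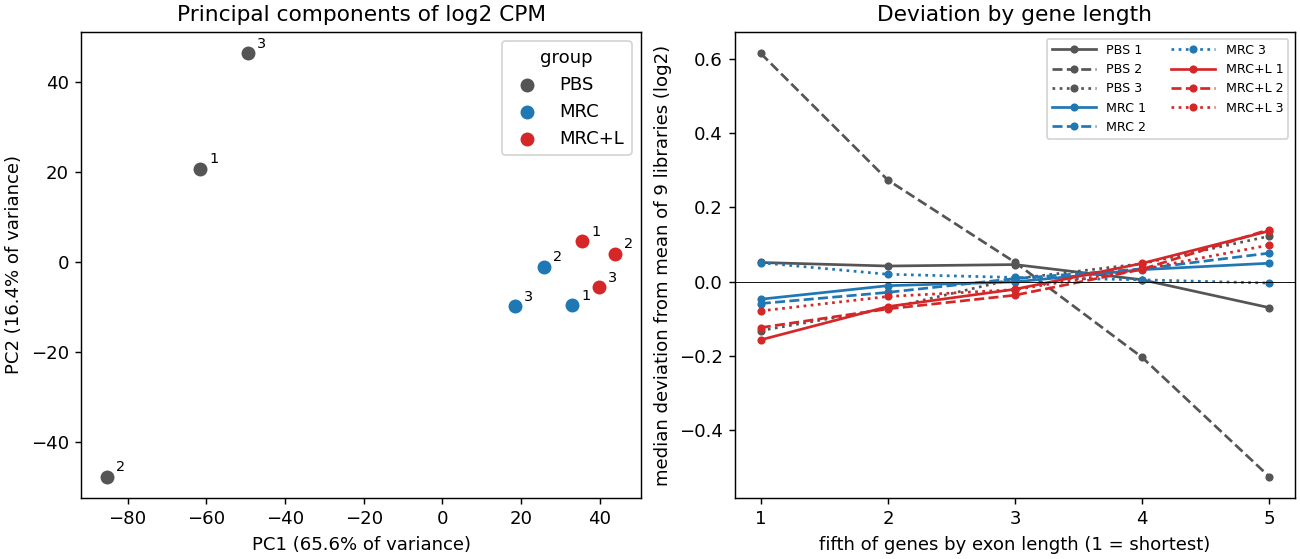
Left, principal component scores of log2 CPM for the 9 libraries, 1 point per library coloured by group, with PBS at negative scores on the first component (-85.3 to -49.4). Right, median deviation in log2 units of each library from the mean of all libraries, by 5 groups of gene length, 1 line per library, with the shortest genes of PBS replicate 2 lying 1.14 above its longest.

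The comparison of MRC with PBS asks what exposure to the particles did without light. Exposed cells held more transcript of NRF2 targets and of the cystine importer. Slc7a11, the light chain of the cystine importer, rose from 48.2 ± 18.8 to 1008 ± 47.3 CPM (log2 fold change 4.39 ± 0.25, 20.9-fold, adjusted p = 2.68e-06, n = 3 per group). Genes of the endoplasmic reticulum stress response rose with it, while genes induced by type I interferon fell, with Sp100 dropping from 275 ± 4.66 to 25.7 ± 3.81 CPM (10.7-fold lower, adjusted p = 6.95e-07). In all, 5050 of 13439 genes differed, 2394 higher and 2656 lower, and 1888 of them differed at least 2-fold (794 higher and 1094 lower). Of 32 lists fixed before the data were examined and tested with camera, 20 were called, and 12 of these calls held with an estimated correlation between genes: apoptosis regulators, ferroptosis and iron, NRF2 targets, ATF4 targets, the unfolded protein response, interferon-stimulated genes, innate sensing, p53 targets, S phase, G2 and mitosis, metal ion response, and mesenchymal genes. With that correlation the camera adjusted p was 0.00678 for interferon-stimulated genes. For the other lists that held it lay between 0.0369 and 0.0481, close to the threshold, far above the values with the preset correlation given below.

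Targets of NRF2, the main transcription factor of the response to electrophiles and oxidants, rose together after MRC. Of 28 tested members 19 rose and 2 fell (20 and 2 adjusted over the list alone), with a median log2 fold change of 1.18 and a camera adjusted p of 7.11e-17. Srxn1, which encodes sulfiredoxin, rose from 132.9 ± 23.6 to 982 ± 54.1 CPM (7.39-fold, adjusted p = 1.77e-06), and Hmox1, which encodes haem oxygenase 1, rose from 36.3 ± 16.5 to 550.0 ± 76.8 CPM (15.2-fold, adjusted p = 8.78e-06). Gclm, a subunit of the enzyme that limits glutathione synthesis, rose 4.19-fold and Nqo1, a quinone reductase, rose 5.04-fold. The members that fell were Ephx1 and Gstm1, of which 1 was still called without MRC replicate 1, 2 or 3. Gsta1, which may share reads with near-identical copies, lay at 0.403 CPM in PBS and 14.8 CPM in MRC (adjusted p = 5.64e-05).

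Of 21 tested genes of ferroptosis and iron handling, 8 rose and 4 fell (9 and 4 adjusted over the list alone; camera adjusted p = 4.58e-05, median 0.41), and the median was 0.25 without PBS replicate 2. Ptgs2, which encodes the inducible cyclooxygenase, rose from 177 ± 29.6 to 1965 ± 414 CPM (log2 fold change 3.48 ± 0.188, 11.1-fold, adjusted p = 2.25e-06). Slc3a2, the partner chain of the cystine importer, rose 3.08-fold. The ferroptosis list shares Slc7a11, Hmox1, Fth1 and Ftl1 with NRF2 targets, and Slc7a11, Slc3a2 and Chac1 with ATF4 targets. It shares Tfrc, Fth1, Ftl1, Slc40a1 and Slc11a2 with the metal ion list. The genes that fell were Gpx4, Chac1, Aifm2 and Nfs1, of which 2 were called without MRC replicate 1. Of 12 tested genes that respond to metal ions 6 rose and 1, Steap4, fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.00084, median 0.59). The count that fell was 2 without PBS replicate 2 and 0 without MRC replicate 1. Slc30a1, a zinc exporter, rose from 8.57 ± 0.61 to 50.4 ± 4.34 CPM (5.87-fold, adjusted p = 1.41e-06). The zinc-binding metallothionein gene Mt1 lay at 113 ± 88.6 CPM in PBS and 493 ± 47.3 CPM in MRC (adjusted p = 0.00333). The list of other antioxidant enzymes was not called (camera adjusted p = 0.176, median -0.44). Of its 18 tested members 2, Cat and Prdx6, rose and 8 fell (2 and 9 adjusted over the list alone). Cat, which encodes catalase, rose 2.35-fold and Gpx1 was 2.69-fold lower. Without PBS replicate 2 that median was -0.19 and 4 members rose; 5 members fell without MRC replicate 1 or MRC replicate 2, and the list was called without PBS replicate 3 (adjusted p = 0.0173).

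Genes of the unfolded protein response, driven by ATF6 and XBP1, rose in 19 of 21 tested members and none fell (19 and 0 adjusted over the list alone; camera adjusted p = 1.73e-13, median 1.01). Hspa5, the main chaperone of the endoplasmic reticulum, rose from 2638 ± 594 to 12792 ± 1166 CPM (log2 fold change 2.28 ± 0.168, 4.85-fold, adjusted p = 9.26e-06) and was the gene with the largest share of counts in 5 of the 6 exposed libraries. Hyou1 and Dnajb9, further chaperones of this compartment, rose 4.12-fold and 3.75-fold. Of 31 tested ATF4 targets of the integrated stress response 22 rose and 1, Chac1, fell (22 and 1 adjusted over the list alone; camera adjusted p = 2.04e-11, median 0.77). Chac1 was not called without PBS replicate 1, MRC replicate 1 or MRC replicate 3. Atf3, a stress-induced transcription factor, rose from 39.4 ± 9.11 to 244 ± 13.9 CPM (6.19-fold, adjusted p = 5.02e-06). Trib3 rose 3.28-fold, Ppp1r15a 4.46-fold, and Ddit3, which encodes CHOP, 3.30-fold (adjusted p = 0.000729).

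Of 23 tested heat shock chaperones 13 rose and 1, Cryab, fell (15 and 1 adjusted over the list alone; camera adjusted p = 0.000346, median 0.48), a call lost at adjusted p = 0.29 with an estimated correlation. Hsp90aa1, a cytosolic chaperone, rose 1.89-fold and Hspa1b, the inducible HSP70, rose from 20.8 ± 12.3 to 193 ± 21.2 CPM (9.31-fold, adjusted p = 0.000381). Hspa1b has a near-identical copy in Hspa1a, so the division of reads between these genes is uncertain. Ribosome biogenesis genes rose in 22 of 30 tested members and none fell (24 and 0 adjusted over the list alone; camera adjusted p = 4.93e-08, median 0.64), with adjusted p = 0.0914 with an estimated correlation. Among them Nop2 rose 1.94-fold and Ddx21, a nucleolar helicase, 2.29-fold.

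Interferon-stimulated genes showed the largest list change. Of 47 tested members 45 fell and 1, Oasl1, rose (the same counts adjusted over the list alone), with a median log2 fold change of -2.43, a camera adjusted p of 1.12e-73, and adjusted p = 0.00678 with an estimated correlation. The number that rose was 2 without PBS replicate 2. Oas2, which senses double-stranded RNA, dropped from 216 ± 20.8 to 16.7 ± 2.11 CPM (log2 fold change -3.69 ± 0.162, 12.9-fold lower, adjusted p = 1.41e-06). Irf7, a transcription factor that drives interferon genes, dropped from 409 ± 105 to 71.2 ± 10.4 CPM (5.75-fold lower), and Oasl2 was 5.30-fold lower. Ifit3 dropped from 81.4 ± 21.1 to 5.35 ± 1.12 CPM and Tgtp1 from 32.8 ± 5.12 to 2.07 ± 0.749 CPM, and both share sequence with close copies, as the Oas and Gbp genes do. The level of Ifi44l was 22.2 CPM in PBS and 0.864 CPM in MRC (adjusted p = 5.55e-05). Cxcl10, an interferon-induced chemokine, rose from 73.9 ± 13.5 to 108.5 ± 9.6 CPM (adjusted p = 0.00945). Ifnb1 lay below the count filter and was not in the edgeR test, with 4 to 15 counts in the PBS and 0 to 4 counts in the exposed libraries.

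Lists of other immune genes also moved mostly downwards, but some of their members are interferon-stimulated genes counted above. Irf7, Ddx58 and Ifih1 of the sensing list are in the interferon list too, as is Zbp1 of the pyroptosis and necroptosis lists. Of 23 tested genes of nucleic acid and TLR sensing 14 fell and 2, Ticam1 and Traf6, rose (the same counts adjusted over the list alone; camera adjusted p = 5.52e-07, median -0.61). The number that rose was 0 without any 1 of the MRC libraries, and 1 without PBS replicate 1, MRC+L replicate 2 or MRC+L replicate 3. Ddx58, the cytosolic sensor RIG-I, was 3.85-fold lower and Ikbke, a kinase downstream of it, 4.15-fold lower. Genes of MHC class I presentation fell in 11 and rose in 2 (Canx and Calr) of 22 tested members (12 and 2 adjusted over the list alone; camera adjusted p = 0.000386, median -0.54), with adjusted p = 0.337 with an estimated correlation. Tapbp was 3.31-fold lower and Tap1, a subunit of the peptide transporter, 2.26-fold lower, whereas H2-K1 had 954 ± 334 CPM in PBS and 683 ± 36.7 CPM in MRC (adjusted p = 0.0883), a difference that was called only without PBS replicate 3 (lowest adjusted p over omissions 0.00922). Calr rose 1.57-fold (adjusted p = 0.00698). Of 13 tested checkpoint genes and ligands of natural killer cells 7 fell and 3 rose (9 and 3 adjusted over the list alone; camera adjusted p = 0.0392, median -0.62), with adjusted p = 0.217 with an estimated correlation. That call was lost without PBS replicate 2 (adjusted p = 0.06), PBS replicate 3 (0.0671) or MRC replicate 3 (0.0542). Pvr rose from 135 ± 10.1 to 377 ± 41.3 CPM and Lgals9, which encodes galectin-9, dropped from 294 ± 56.5 to 71.9 ± 8.38 CPM. Cd274, which encodes PD-L1, had 8.74 ± 1.52 CPM in PBS and 6.32 ± 1.05 CPM in MRC (adjusted p = 0.0693); it was called without PBS replicate 2 or PBS replicate 3. NF-kB targets and cytokines were not called as a list (camera adjusted p = 0.0643, median -0.31), with 6 members higher and 14 lower of 32 tested (the same counts adjusted over the list alone). The list was called without PBS replicate 1 (adjusted p = 0.0383), PBS replicate 3 (0.0186) or MRC replicate 3 (0.034). Ccl2, a chemokine for monocytes, was 5.52-fold lower, and the cytokine gene Il6 lay at 1.09 CPM in PBS and 14.99 CPM in MRC (adjusted p = 5.26e-06).

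Pyroptosis is a lytic cell death carried out by gasdermins, and it is named in the title of the series. The counts measure transcripts and not cleavage of gasdermin protein, so they cannot show whether cells died in this way. Gsdmd, which encodes the gasdermin cleaved by inflammatory caspases, dropped from 58.3 ± 14.7 to 24.96 ± 0.999 CPM (log2 fold change -1.22 ± 0.163, 2.34-fold lower, adjusted p = 0.000306). Gsdme, which encodes another gasdermin, had 31.0 ± 6.77 CPM in PBS and 30.3 ± 2.83 CPM in MRC (-0.03 ± 0.157, adjusted p = 0.883). Casp1 (9.52 and 11.8 CPM, adjusted p = 0.387) and Casp4 (12.6 and 12.8 CPM, adjusted p = 0.924) were not called either, although Casp1 was called without PBS replicate 2 (lowest adjusted p over omissions 0.00294). Zbp1 was 8.09-fold lower, Casp8 1.87-fold lower and Hmgb1 1.73-fold lower, and Il18 lay at 3.78 CPM in PBS and 1.71 CPM in MRC (adjusted p = 0.0114). Nlrp3 had 0 to 7 counts in any library, and Il1b had no count in PBS and 0 to 6 in exposed libraries, so neither was tested. Of 17 tested pyroptosis genes 9 fell and 1, Gsdmc4, rose (10 and 1 adjusted over the list alone; camera adjusted p = 0.000386, median -0.79), with adjusted p = 0.0914 with an estimated correlation. The number that rose was 0 without PBS replicate 1, MRC replicate 1 or MRC replicate 3, and 2 without PBS replicate 2.

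Apoptosis regulators fell in 16 and rose in 1 (Tnfrsf10b) of 28 tested members (18 and 2 adjusted over the list alone; camera adjusted p = 0.0018, median -0.49). The list holds genes for and against cell death: Bcl2l1, which encodes the survival factor BCL-XL, was 1.89-fold lower, and Casp8 also fell. Among them 4 rose without PBS replicate 2, 2 without PBS replicate 3 and 3 with the length trend removed. The necroptosis list was not called (camera adjusted p = 0.0832, median -0.03), with 1 member (Pgam5) higher and 4 (Mlkl, Zbp1, Tnfsf10 and Casp8) lower of 11 tested, the same counts adjusted over the list alone. Its median moved to between -0.133 and -0.00458 with 1 library left out, and 2 members rose without PBS replicate 2. Of 24 tested p53 targets 10 rose and 5 fell (the same counts adjusted over the list alone; camera adjusted p = 0.00173, median 0.32). The count that fell was 3 without MRC replicate 1 or MRC replicate 2. Plk2 rose from 47.9 ± 1.88 to 485 ± 58.5 CPM (10.1-fold, adjusted p = 6.95e-07) and Mdm2 rose 1.78-fold, while Cdkn1a, which encodes p21, had 48.7 ± 3.68 and 52.5 ± 3.64 CPM (adjusted p = 0.483).

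Genes of the cell cycle fell after MRC. Of 30 tested genes of S phase 21 fell and none rose (24 and 1 adjusted over the list alone; camera adjusted p = 1.27e-06, median -0.54), and of 31 genes of G2 and mitosis 25 fell and none rose (the same counts adjusted over the list alone; camera adjusted p = 6.76e-07, median -0.65). The count of S phase genes that rose was 2 without PBS replicate 2 and 1 without MRC replicate 2. Tk1, a thymidine kinase, dropped from 183 ± 41.2 to 46.3 ± 6.09 CPM (3.95-fold lower, adjusted p = 1.92e-05), Mcm6, part of the replicative helicase, was 1.87-fold lower and Nusap1, a spindle protein gene, 1.87-fold lower. Mki67, the proliferation marker, dropped from 864 ± 270.4 to 510 ± 28.1 CPM (1.70-fold lower, adjusted p = 0.013), and this call was lost without MRC replicate 1 (highest adjusted p over omissions 0.0547). Replication-dependent histones were not called as a list (camera adjusted p = 0.0969, median 0.77; called without MRC replicate 2, adjusted p = 0.0356), although 4 of 11 tested members rose and none fell, the same counts adjusted over the list alone. Histone genes have many near-identical copies, so their counts are uncertain. Immediate early and AP-1 genes went both ways, with 12 higher and 13 lower of 33 tested (the same counts adjusted over the list alone; camera adjusted p = 0.726). The median of this list was 0.13 while its mean was -0.04 and the test pointed upwards; the median was 0.0160 without PBS replicate 3 and 0.0830 without MRC replicate 3. Egr1 dropped from 54.6 ± 9.0 to 4.62 ± 0.594 CPM (11.8-fold lower, adjusted p = 2.25e-06) and Dusp1, a phosphatase of MAP kinases, rose 5.12-fold.

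Among genes of metabolism, cholesterol synthesis fell in 16 and rose in 2 (Sqle and Ggps1) of 25 tested members, the same counts adjusted over the list alone (camera adjusted p = 0.000336, median -0.62), with adjusted p = 0.0914 with an estimated correlation. The count that fell was 10 without MRC replicate 1 or MRC replicate 2; the count that rose was 0 without MRC replicate 1 and 1 without PBS replicate 1 or MRC replicate 3. Hmgcs1 was 1.94-fold lower. Mesenchymal and matrix genes fell in 10 and rose in 1 of 16 (11 and 2 adjusted over the list alone; camera adjusted p = 0.000343, median -0.76). The number that rose was 2 without PBS replicate 2 and 3 without PBS replicate 3. Mmp3 and Mmp9, secreted proteases of the matrix, were 3.86-fold and 2.96-fold lower. The lists of glycolysis (3 higher and 10 lower of 20, 3 and 11 adjusted over the list alone; camera adjusted p = 0.09) and lysosome and autophagy (9 higher and 6 lower of 33, the same adjusted over the list alone; camera adjusted p = 0.274) were not called. Glycolysis was called without PBS replicate 3 (adjusted p = 0.0252), and its median of -0.36 was -0.23 without PBS replicate 2; 10 lysosome genes fell without PBS replicate 3. Sqstm1, an autophagy receptor and NRF2 target, rose 4.32-fold. The HIF target list held 5 higher and 10 lower genes of 24 (6 and 10 adjusted over the list alone), and its median was -0.09 while the test pointed upwards (camera adjusted p = 0.802). The number lower was 3 to 6 without PBS replicate 1, MRC+L replicate 3 or any 1 of the MRC libraries, and 8 genes were higher without PBS replicate 2 or PBS replicate 3. Ndrg1 rose 2.77-fold and Vegfa 1.89-fold, whereas Egln3 lay at 200 to 222 CPM in the PBS libraries and 83.9 to 99.9 CPM in the MRC libraries. Fatty acid synthesis was not called (camera adjusted p = 0.917, 2 higher and 3 lower of 14, 2 and 4 adjusted over the list alone); without 1 library its counts moved over 1 to 4 higher and 1 to 8 lower, the last without PBS replicate 2. Epithelial markers were not called (camera adjusted p = 0.374, 5 higher and 3 lower of 13, the same adjusted over the list alone); 3 were higher without PBS replicate 1, MRC replicate 1 or MRC replicate 3, and 5 were lower without PBS replicate 2. Krt18 was 2.87-fold lower and Esrp2, a splicing regulator of epithelia, rose 2.74-fold.

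Results for genes of the respiratory chain changed with the libraries in the fit, PBS replicate 2 among them. Of 40 tested nuclear-encoded genes 17 fell and none rose (24 and 0 adjusted over the list alone; camera adjusted p = 0.000911, median -0.59), with adjusted p = 0.596 with an estimated correlation. Without PBS replicate 2 the median was -0.25 with 3 higher and 19 lower; the count that fell was 32 without PBS replicate 3 and 9 to 11 without any 1 of the MRC libraries. Sdha, a subunit of complex II, was 1.53-fold lower (adjusted p = 0.000684). Of 12 mitochondrially encoded genes 8 fell and none rose (10 and 0 adjusted over the list alone; camera adjusted p = 0.0213, median -0.71), with adjusted p = 0.52 with an estimated correlation. That call was lost without PBS replicate 2 (median -0.42, adjusted p = 0.0654) or MRC replicate 2 (0.0505). The number of genes that fell was 1 without MRC replicate 2, 2 without MRC replicate 1, and 4 or 5 without PBS replicate 1, MRC replicate 3 or any 1 of the MRC+L libraries. mt-Cytb dropped from 4431 ± 276 to 2809 ± 332 CPM (1.58-fold lower, adjusted p = 0.00194). No cytosolic ribosomal protein gene of 48 was called by edgeR, also when adjusted over the list alone (median -0.04, camera adjusted p = 0.887 with an upward direction). Without PBS replicate 2, 42 of them rose with a median of 0.40 (camera adjusted p = 1.49e-05), and 2 fell without PBS replicate 3. With the length trend removed 4 rose with a median of 0.122.

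Markers of other cell types stayed low or mixed. Of 22 leukocyte markers 3 passed the count filter and were too few for a list test; Cd68 rose from 9.38 ± 2.36 to 19.3 ± 2.81 CPM (adjusted p = 0.00195). Among 6 tested markers of fibroblasts and endothelium 2 rose and 3 fell, the same counts adjusted over the list alone (camera adjusted p = 0.472); 1 rose without any 1 of the PBS libraries, MRC replicate 1 or MRC replicate 2. Of 4 tested nuclear-retained RNAs, also too few for a list test, Malat1 rose 2.19-fold (adjusted p = 0.00255) and Tug1 was 1.39-fold lower (adjusted p = 0.0147), the latter not called without MRC replicate 2. A few genes near the floor in PBS had clear counts in MRC, among them Tbcel (0.217 and 10.7 CPM), Sstr5 (0.316 and 14.9 CPM) and Ptx3 (0.113 and 6.35 CPM). Members given here only as the exceptions within a list were picked after their values were seen.

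**Figure D2:**
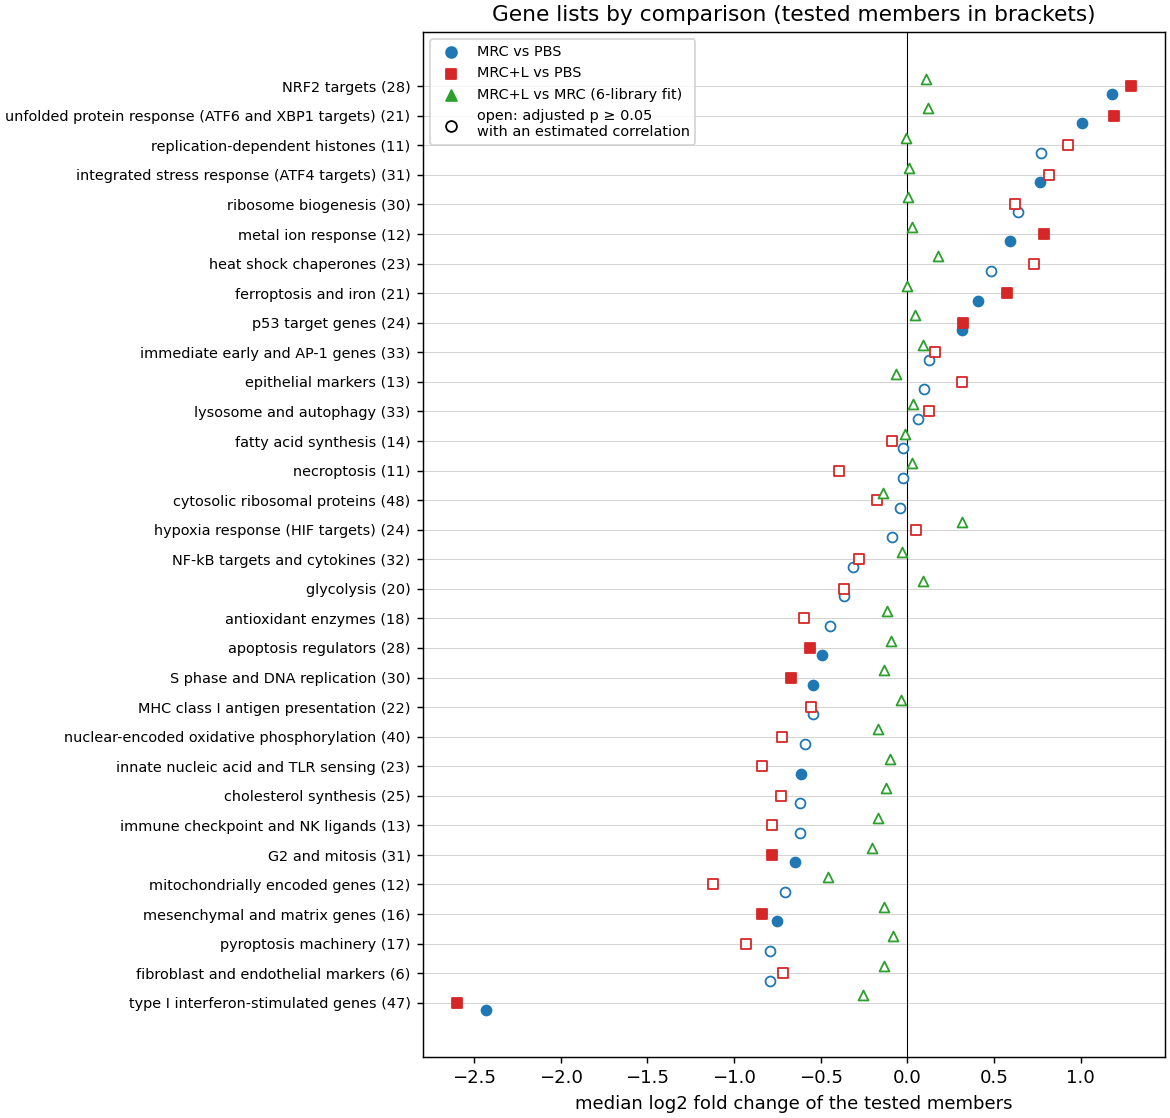
Median log2 fold change of the tested members of 32 gene lists, 1 row per list, for MRC against PBS, MRC+L against PBS and MRC+L against MRC in the fit of 6 libraries; filled points mark lists with an adjusted p under 0.05 with an estimated correlation. Interferon-stimulated genes lie lowest at -2.43 and -2.60 against PBS, and NRF2 targets highest at 1.18 and 1.29.

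**Figure D3:**
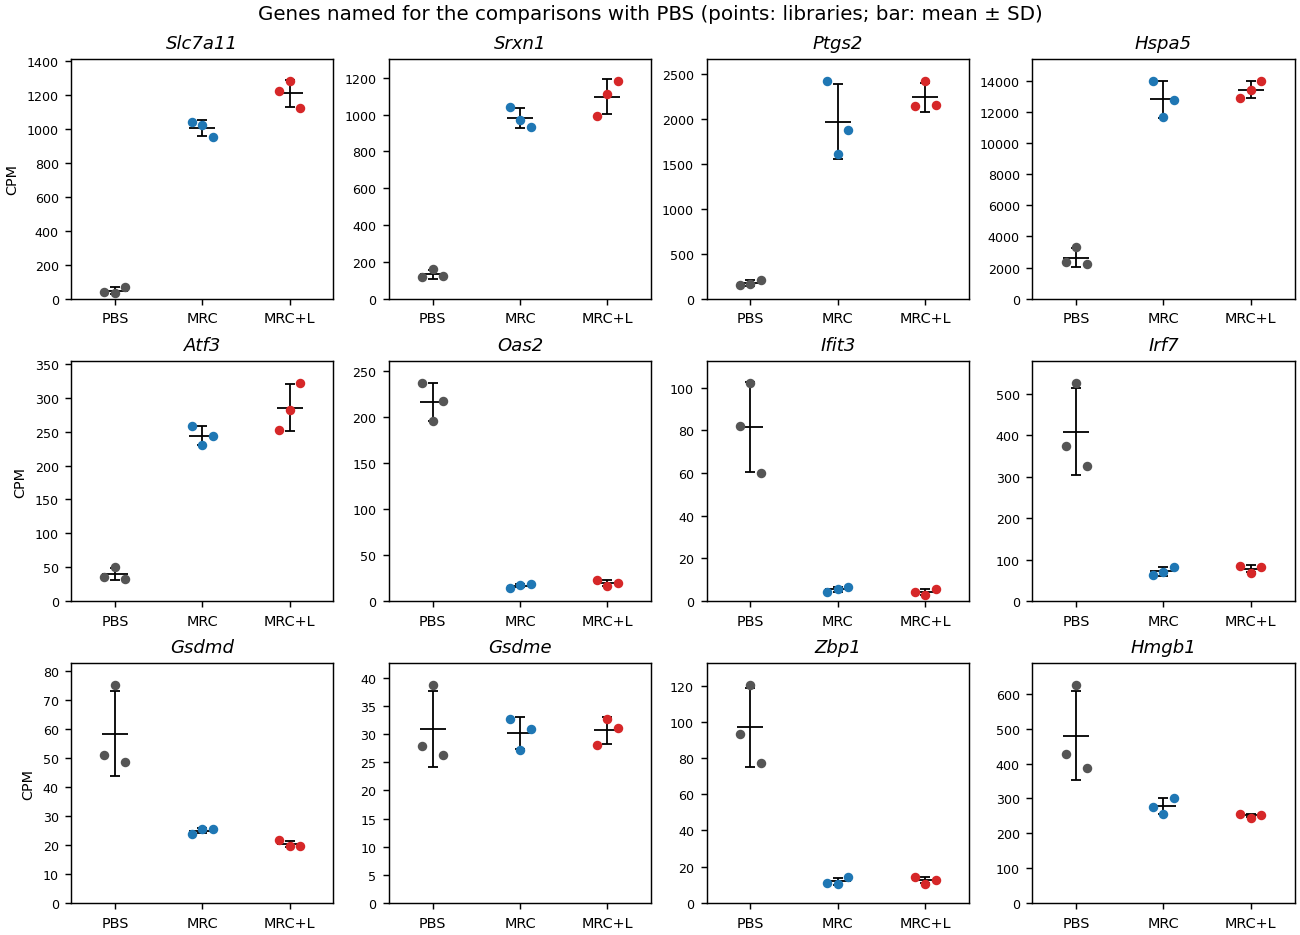
Level in CPM of 12 genes in the PBS, MRC and MRC+L libraries, 1 point per library, with a bar for the mean and SD of n = 3. Slc7a11 rises from 48.2 CPM in PBS to 1008 CPM in MRC, Oas2 falls from 216 to 16.7 CPM, and Gsdme lies at 31.0, 30.3 and 30.7 CPM in the 3 groups.

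The main genes of this comparison lie at the following places in GRCm39, from the deposited tables. Slc7a11 (ENSMUSG00000027737) spans chromosome 3 from 49846975 to 50398063, Hspa5 (ENSMUSG00000026864) chromosome 2 from 34661982 to 34667559, and Oas2 (ENSMUSG00000032690) chromosome 5 from 120868398 to 120887918. Gsdmd (ENSMUSG00000022575) spans chromosome 15 from 75734176 to 75739257 and Gsdme (ENSMUSG00000029821) chromosome 6 from 50165868 to 50240842. Counts are sums over the exons of each gene, untranslated regions included.

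The comparison of MRC+L with PBS asks what the particles and light did together. No group had light alone, so the comparison cannot separate light from particles, and the labels do not give when within the 12 h the light was applied. The same groups led: Slc7a11 rose from 48.2 ± 18.8 to 1213 ± 80.0 CPM (log2 fold change 4.66 ± 0.253, 25.2-fold, adjusted p = 1.53e-06, n = 3 per group) and Hmox1 from 36.3 ± 16.5 to 832 ± 12.8 CPM (4.52 ± 0.294, 22.9-fold, adjusted p = 3.33e-06). Hspa1b, the inducible HSP70, rose from 20.8 ± 12.3 to 1008 ± 244 CPM (5.60 ± 0.493, 48.6-fold, adjusted p = 1.9e-05), with the limit on its near-identical copy given above. Oas2 dropped from 216 ± 20.8 to 19.1 ± 3.29 CPM (11.3-fold lower, adjusted p = 8.75e-07). In all, 6212 of 13439 genes differed, 2926 higher and 3286 lower, and 2510 at least 2-fold (1113 higher and 1397 lower). Of the 32 lists 22 were called, and 10 held with an estimated correlation: apoptosis regulators, ferroptosis and iron, NRF2 targets, the unfolded protein response, interferon-stimulated genes, p53 targets, S phase, G2 and mitosis, metal ion response, and mesenchymal genes. With that correlation the camera adjusted p was 0.0191 for interferon-stimulated genes. For the other lists that held it lay between 0.0367 and 0.0413, close to the threshold.

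NRF2 targets rose in 20 and fell in 1 (Gstm1) of 28 tested members, the same counts adjusted over the list alone (camera adjusted p = 1.59e-16, median 1.29); 3 fell without PBS replicate 3 and none without MRC+L replicate 2 or MRC+L replicate 3. Srxn1 rose 8.25-fold to 1097 ± 95.2 CPM. Ferroptosis and iron genes rose in 9 and fell in 5 of 21, the same counts adjusted over the list alone (camera adjusted p = 0.000237, median 0.58, and 0.26 without PBS replicate 2). Metal ion genes rose in 7 and fell in 1 of 12, the same adjusted over the list alone (camera adjusted p = 0.00153, median 0.79); 2 fell without PBS replicate 2. The unfolded protein response rose in 19 of 21 members with none lower, also when adjusted over the list alone (camera adjusted p = 3.04e-13, median 1.19). Hspa5 rose 5.09-fold to 13429 ± 532 CPM. ATF4 targets rose in 23 and fell in 2 (Chac1 and Pck2) of 31, the same adjusted over the list alone (camera adjusted p = 7.62e-10, median 0.82), with adjusted p = 0.0556 with an estimated correlation. Heat shock chaperones rose in 15 and fell in 1 (Cryab) of 23, the same adjusted over the list alone (camera adjusted p = 7.62e-07, median 0.73), with adjusted p = 0.143 with an estimated correlation. Hsph1 rose 3.23-fold and Hsp90aa1 2.53-fold. Ribosome biogenesis genes rose in 22 of 30 with none lower, also over the list alone (camera adjusted p = 7.62e-07, median 0.62), with adjusted p = 0.124 with an estimated correlation; 1 fell without PBS replicate 3.

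Interferon-stimulated genes fell in 45 of 47 tested members and none rose, the same counts adjusted over the list alone (camera adjusted p = 2.95e-71, median -2.60); 2 rose without PBS replicate 2. Nucleic acid and TLR sensing genes fell in 14 and rose in 3 of 23 (15 and 4 adjusted over the list alone; camera adjusted p = 1.65e-06, median -0.84), with adjusted p = 0.0556 with an estimated correlation; 5 rose without PBS replicate 3. MHC class I genes fell in 11 and rose in 3 of 22 (14 and 4 adjusted over the list alone; camera adjusted p = 0.00131, median -0.56), with adjusted p = 0.392 with an estimated correlation; 5 rose without PBS replicate 2. Checkpoint genes and natural killer cell ligands fell in 9 and rose in 2 (Pvr and H60b) of 13 (9 and 3 adjusted over the list alone; camera adjusted p = 0.0199, median -0.78), with adjusted p = 0.132 with an estimated correlation. Cd274 dropped from 8.74 ± 1.52 to 5.32 ± 0.301 CPM (adjusted p = 0.0113). NF-kB targets fell in 15 and rose in 4 of 32 (16 and 4 adjusted over the list alone; camera adjusted p = 0.0434, median -0.28), with adjusted p = 0.475 with an estimated correlation. That call was lost without PBS replicate 2 (adjusted p = 0.0905, 7 higher), MRC replicate 2 (0.06) or MRC+L replicate 2 (0.0788), and 7 were higher with the length trend removed.

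Of the pyroptosis list 10 of 17 members fell and 1, Gsdmc4, rose, the same counts adjusted over the list alone (camera adjusted p = 0.000855, median -0.93), with adjusted p = 0.124 with an estimated correlation. The number that rose was 3 without PBS replicate 2 and 0 without any 1 of the other libraries apart from PBS replicate 3. Gsdmd dropped to 20.3 ± 1.12 CPM (log2 fold change -1.52 ± 0.165, 2.87-fold lower, adjusted p = 6.51e-05). Gsdme had 30.7 ± 2.33 CPM (-0.02 ± 0.157, adjusted p = 0.945). Casp1 had 10.1 ± 1.65 CPM (adjusted p = 0.823) and Casp4 13.4 ± 1.75 CPM (adjusted p = 0.742), and both were called without PBS replicate 2. Hmgb1 was 1.91-fold lower and Il18 lay at 1.27 CPM (adjusted p = 0.002). Apoptosis regulators fell in 17 and rose in 3 (Tnfrsf10b, Birc2 and Cflar) of 28, the same adjusted over the list alone (camera adjusted p = 0.000773, median -0.56); the number that rose was 1 without PBS replicate 1 and 5 without PBS replicate 2 or with the length trend removed. Necroptosis genes were not called as a list (camera adjusted p = 0.063, 1 higher and 6 lower of 11, 3 and 6 adjusted over the list alone); the list was called without PBS replicate 2 (adjusted p = 0.0436, 2 higher) or PBS replicate 3 (0.0488, 3 higher).

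S phase genes fell in 25 of 30 and 1, Ccne2, rose, the same adjusted over the list alone (camera adjusted p = 1.79e-07, median -0.67); none rose without PBS replicate 1, MRC replicate 3, MRC+L replicate 2 or MRC+L replicate 3. Genes of G2 and mitosis fell in 26 of 31 with none higher (27 and 0 adjusted over the list alone; camera adjusted p = 4.15e-09, median -0.78), and p53 targets rose in 12 and fell in 5 of 24 (the same adjusted over the list alone; camera adjusted p = 0.00151, median 0.32). Cdkn1a rose to 61.6 ± 6.11 CPM (1.26-fold, adjusted p = 0.0326), a call lost without PBS replicate 1, PBS replicate 3, MRC replicate 3, MRC+L replicate 1 or MRC+L replicate 2 (highest adjusted p 0.121). Mki67 dropped to 525 ± 37.4 CPM (1.65-fold lower, adjusted p = 0.0142), a call lost without MRC+L replicate 2 or MRC+L replicate 3 (highest adjusted p 0.0552). Cholesterol synthesis genes fell in 18 and rose in 2 of 25 (19 and 2 adjusted over the list alone; camera adjusted p = 0.000131, median -0.73), with adjusted p = 0.0727 with an estimated correlation. Mesenchymal genes fell in 10 and rose in 3 of 16 (11 and 3 adjusted over the list alone; camera adjusted p = 0.000372, median -0.84). HIF targets rose in 11 and fell in 3 of 24 (11 and 5 adjusted over the list alone; camera adjusted p = 0.0402, median 0.05), with adjusted p = 0.543 with an estimated correlation. That call was lost without PBS replicate 3 (median -0.00344, adjusted p = 0.0784, 5 lower) or MRC+L replicate 1 (0.0267, adjusted p = 0.166); the median was 0.226 without PBS replicate 2 and 0.143 with the length trend removed, and the number lower was 0 or 1 without PBS replicate 1, MRC+L replicate 2, MRC+L replicate 3 or any 1 of the MRC libraries.

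Nuclear-encoded genes of the respiratory chain fell in 28 of 40 with none higher (29 and 0 adjusted over the list alone; camera adjusted p = 0.000131, median -0.72), with adjusted p = 0.543 with an estimated correlation. The median was -0.45 without PBS replicate 2, the library with the length trend, when 2 members rose; 18 fell without MRC+L replicate 1 or MRC+L replicate 2. All 12 tested mitochondrially encoded genes fell, also when adjusted over the list alone (camera adjusted p = 0.000773, median -1.12), with adjusted p = 0.375 with an estimated correlation. mt-Cytb dropped from 4431 ± 276 to 2297 ± 87.1 CPM (1.93-fold lower, adjusted p = 0.000175). No cytosolic ribosomal protein gene of 48 was called by edgeR (median -0.18, camera adjusted p = 0.612). Without PBS replicate 2, 30 rose with a median of 0.26 (camera adjusted p = 0.00718), and without PBS replicate 3, 8 fell with a median of -0.41 (camera adjusted p = 0.0488). With the length trend removed 3 rose with a median of 0.0553. Of the lists not named so far in this comparison, none was called: antioxidant enzymes (camera adjusted p = 0.113, but 0.0375 without PBS replicate 1 and 0.0106 without PBS replicate 3), immediate early genes (0.442), histones (0.142), fatty acid synthesis (0.784), glycolysis (0.327), lysosome and autophagy (0.275), epithelial markers (0.47), and fibroblast and endothelial markers (0.445).

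The MRC+L and MRC profiles were close to each other when each was compared with PBS. Of the genes called, 2241 were higher and 2504 lower in both comparisons, and no gene was called in opposite directions by edgeR. Among the shared genes, Slc7a11 was 20.9-fold and 25.2-fold higher and Sp100 10.7-fold and 11.2-fold lower. Both comparisons use the same PBS libraries. In 20 simulations of unchanged groups all 9 libraries, PBS included, were drawn anew, each gene independently with the spread of its group. The simulations gave means of 1.1 genes higher and 0.25 lower in both, whereas independent lists of these lengths would share 521 and 649. No gene was changed in the simulations, so few calls and a small overlap were fixed by their setting. They cannot show how much overlap the shared PBS libraries give where many genes are called in each comparison. Deviations that many genes share in the real PBS libraries, such as the length trend of PBS replicate 2, were absent from the simulations. Fold changes correlated across genes at r = 0.954, against 0.798 in the simulations; genes are not independent replicates. The covariance was 0.833 against 0.0793 simulated, a difference of 0.754. The PBS libraries were too few to split, so part of the excess may come from the shared controls. A test across the 3 groups together called 5403 genes.

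The comparison of MRC+L with MRC asks what the light added. In the fit of all 9 libraries edgeR called no gene of 13439, with 573 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.0882; DESeq2 called 25 and limma-voom none. A fit of only the 6 MRC and MRC+L libraries, whose spread was smaller (0.0707), called 654 of 12955 genes, 406 higher and 248 lower. With the length trend removed 432 were called, 205 higher and 227 lower, and with the trend removed and a replicate block 357, 173 higher and 184 lower. Fold changes hardly differed between the fits, since all 654 genes had the same sign in both and the largest difference was 0.0192 on the log2 scale. The fit of all 9 libraries was the test set in advance, and it called no gene. Values below come from the fit of 6 libraries, an alternative to it. Changes there were small: the median size of a called change was 0.32 on the log2 scale, and 30 genes differed at least 2-fold (26 higher and 4 lower). The count was 1015 without MRC replicate 2, 193 without MRC replicate 3, and 382, 137 and 297 without MRC+L replicates 1, 2 and 3. Of the 654 genes, 367 were also called between MRC and PBS, 334 in the same direction and 33 in the opposite direction. Both comparisons use the MRC libraries, and in the fit of 9 libraries their fold changes correlated at r = 0.220, against -0.318 in simulations of unchanged groups (covariance 0.059 against -0.0201).

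Several heat shock chaperone genes rose with light. Hspa1b rose from 193 ± 21.2 to 1008 ± 244 CPM (log2 fold change 2.39 ± 0.113, 5.23-fold, adjusted p = 2.14e-12, n = 3 per group), and its copy Hspa1a lay at 2.58 CPM in MRC and 18.9 CPM in MRC+L (adjusted p = 6.88e-10). The co-chaperone genes Dnaja4 and Dnajb1 rose 2.41-fold (adjusted p = 1.48e-06) and 1.65-fold (adjusted p = 2.28e-06), and Hsph1 rose 1.66-fold. Of 23 tested heat shock chaperones 9 rose and none fell (11 and 1 adjusted over the list alone; camera adjusted p = 4.88e-19, median 0.18), with adjusted p = 0.451 with an estimated correlation, and the median was 0.32 without MRC replicate 1. In the fit of 9 libraries adjusted over the list alone 6 rose. Hmox1 rose from 550.0 ± 76.8 to 832 ± 12.8 CPM (0.60 ± 0.075, 1.52-fold, adjusted p = 4.66e-05). NRF2 targets rose in 4 of 28 (Hmox1, Gclc, Slc7a11 and Gstm1; 8 adjusted over the list alone; camera adjusted p = 3.12e-05, median 0.11), with adjusted p = 0.233 with an estimated correlation; 1 rose without MRC replicate 3 or MRC+L replicate 2 and 2 without MRC+L replicate 1. Jun, a stress-induced AP-1 factor, rose 1.41-fold (adjusted p = 0.000235).

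HIF targets rose in 15 of 23 tested members and none fell (17 and 0 adjusted over the list alone; camera adjusted p = 2.92e-14, median 0.32), with adjusted p = 0.451 with an estimated correlation. The count was 4 without MRC+L replicate 1. Adjusted over the list alone in the fit of 9 libraries, no HIF target was called, nor any member of the lists of NRF2 targets, the unfolded protein response, glycolysis, S phase, G2 and mitosis, the nuclear-encoded respiratory chain, ribosomal proteins, antioxidant enzymes or cholesterol synthesis. Ero1l rose from 531 ± 39.3 to 784 ± 160.5 CPM (1.48-fold, adjusted p = 0.00138) and Bnip3 from 87.8 ± 15.7 to 129 ± 23.4 CPM (1.48-fold, adjusted p = 0.00395). In the PBS libraries Ero1l lay at 341 to 482 CPM, below MRC+L. Bnip3 lay at 116 to 151 CPM there, so its mean in MRC+L was not above PBS. Glycolysis genes rose in 2 of 20 (Eno2 and Slc2a1; 3 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.029, median 0.09), with adjusted p = 0.571 with an estimated correlation, and 1 rose and 1 fell without MRC+L replicate 1. The unfolded protein response rose in 3 of 21 (6 adjusted over the list alone; camera adjusted p = 0.000595, median 0.12), with adjusted p = 0.474 with an estimated correlation; the count was 5 without MRC replicate 2, 1 without MRC replicate 3 or MRC+L replicate 2, and 0 without MRC+L replicate 3.

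Id1 and Id3, inhibitors of differentiation downstream of BMP signalling, fell with light. Id1 dropped from 36.9 ± 5.3 to 15.2 ± 1.09 CPM (log2 fold change -1.28 ± 0.11, 2.42-fold lower, adjusted p = 2.08e-07) and Id3 from 44.0 ± 7.75 to 19.5 ± 3.5 CPM (2.27-fold lower, adjusted p = 4.54e-06). Interferon-stimulated genes fell in 12 of 47 with none higher (18 and 0 adjusted over the list alone; camera adjusted p = 2.92e-14, median -0.26), with adjusted p = 0.474 with an estimated correlation, and the median was -0.16 without MRC replicate 3. In the fit of 9 libraries adjusted over the list alone 5 fell. Ifit1 dropped from 46.2 ± 4.25 to 24.5 ± 1.88 CPM (-0.91 ± 0.0919, 1.88-fold lower, adjusted p = 2.28e-06), Rsad2 was 1.51-fold lower, and Cxcl10, which MRC had raised, dropped to 77.5 ± 2.09 CPM (1.40-fold lower, adjusted p = 0.000353). The granulocyte factor gene Csf3 and the chemokine gene Ccl5 were 1.40-fold and 1.42-fold lower.

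Mitochondrially encoded genes fell in 6 of 12 with none higher (7 and 0 adjusted over the list alone; camera adjusted p = 1.98e-12, median -0.46), with adjusted p = 0.451 with an estimated correlation. In the fit of 9 libraries adjusted over the list alone 2 fell. mt-Nd5 dropped from 1677 ± 88.5 to 1179 ± 23.6 CPM (1.42-fold lower, adjusted p = 4.68e-05) and mt-Nd6, which lies on the opposite strand to its neighbours and is uncertain in unstranded counts, was 1.53-fold lower. Of 4 tested nuclear-retained RNAs, too few for a list test, 2 rose and 0 fell (median 0.252). With 1 library left out 0 to 2 of them rose, and their median was 0.201 to 0.335. Nuclear-encoded genes of the respiratory chain fell in 5 of 40 (15 adjusted over the list alone; camera adjusted p = 7.13e-09, median -0.17), with adjusted p = 0.474 with an estimated correlation. The count was 9 without MRC replicate 2, 0 without MRC replicate 3 or any 1 of the MRC+L libraries, and 1 with the length trend removed (median -0.115). G2 and mitosis genes fell in 10 of 31 (22 adjusted over the list alone; camera adjusted p = 1.03e-11, median -0.20), with adjusted p = 0.451 with an estimated correlation; the count was 0 without MRC replicate 3 or MRC+L replicate 2, 2 without MRC+L replicate 3 and 4 without MRC+L replicate 1. S phase genes fell in 3 of 30 (Rrm2, Tk1 and Chaf1b; 4 adjusted over the list alone; camera adjusted p = 0.000125, median -0.14), with adjusted p = 0.474 with an estimated correlation, and in none without MRC replicate 3, MRC+L replicate 2 or MRC+L replicate 3. Cytosolic ribosomal proteins (camera adjusted p = 5e-08, median -0.14), antioxidant enzymes (0.0198, median -0.12) and cholesterol synthesis (0.0489, median -0.12) were also called, with at most 1 member called each and with adjusted p = 0.549, 0.474 and 0.491 with an estimated correlation; 10 ribosomal protein genes fell without MRC replicate 2, and 2 cholesterol genes without MRC+L replicate 1. The median of ribosomal proteins was -0.0687 without MRC replicate 3 and -0.085 without MRC+L replicate 1, and that of antioxidant enzymes was -0.075 without MRC replicate 3. Altogether 13 lists were called in this fit and 12 in the fit of 9 libraries, none of them with an estimated correlation. Calls of cholesterol synthesis, ribosomal proteins and the unfolded protein response in the fit of 9 were each lost without at least 1 library (highest adjusted p 0.128, 0.209 and 0.0578).

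No gene of pyroptosis was called between MRC+L and MRC by edgeR in either fit. In the fit of 6 libraries the list had camera adjusted p = 0.172 over 14 tested members, also with no member called adjusted over the list alone, and 2 members fell without MRC replicate 2. Gsdmd had the smallest p, with 24.96 ± 0.999 CPM in MRC and 20.3 ± 1.12 CPM in MRC+L (-0.29 ± 0.0969, adjusted p = 0.0808). Gsdme had 30.3 ± 2.83 and 30.7 ± 2.33 CPM (0.02 ± 0.0939, adjusted p = 0.923). Bcl2l1, which encodes BCL-XL, dropped from 57.2 ± 2.14 to 40.1 ± 1.47 CPM (1.42-fold lower, adjusted p = 0.000393), and apoptosis regulators were called as a list in the fit of 9 libraries (camera adjusted p = 0.0237, lower; 0.196 with an estimated correlation; 1 member lower adjusted over the list alone) but not in the fit of 6 (0.0562). The call in the fit of 9 was lost without PBS replicate 1 (adjusted p = 0.0604), PBS replicate 2 (0.0655), MRC replicate 2 (0.0578), MRC replicate 3 (0.203, with the median moving from -0.0999 to -0.0322) or MRC+L replicate 3 (0.126). Calr, Hmgb1, Cd274 and H2-K1 were not called (adjusted p = 0.435, 0.225, 0.485 and 0.987).

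**Figure D4:**
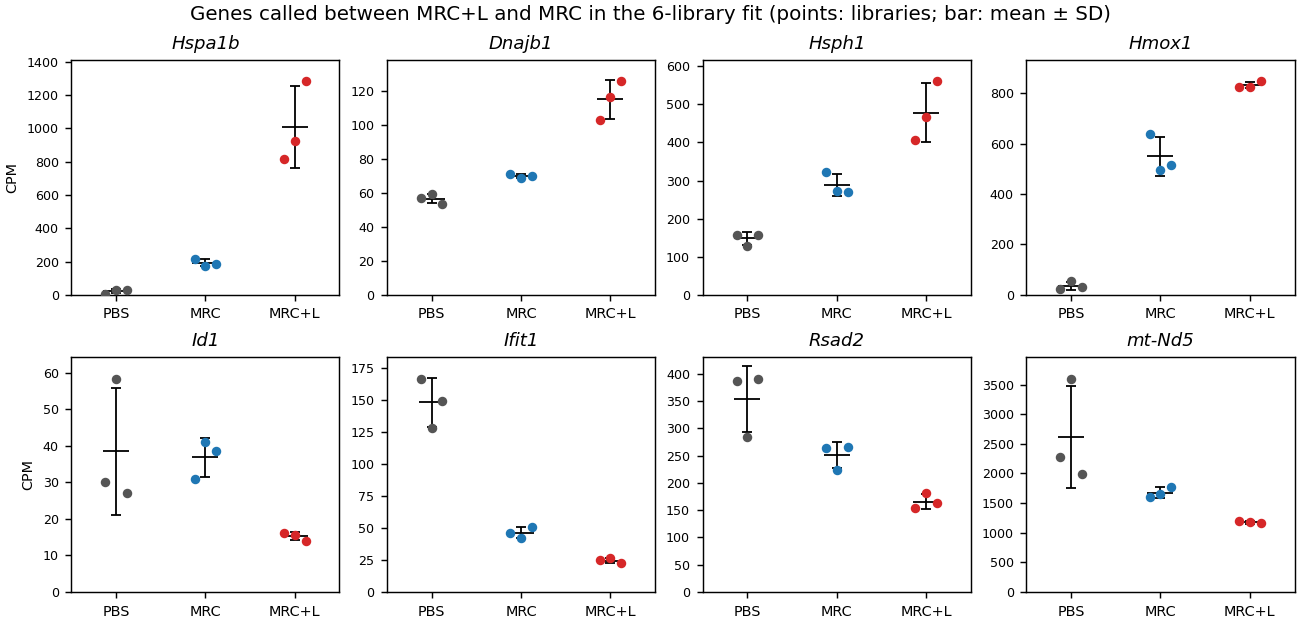
Level in CPM of 8 genes in the PBS, MRC and MRC+L libraries, 1 point per library, with a bar for the mean and SD of n = 3. Hspa1b lies at 193 CPM in MRC and 1008 CPM in MRC+L, Id1 at 36.9 and 15.2 CPM, and mt-Nd5 at 1677 and 1179 CPM.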

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

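The weighted voom fits, the GC correction, the list tests with the length trend removed or in the fit of 6 libraries, and the alternatives within the fit of 6 libraries were chosen after seeing the data, and the others before. The counts of 5050 genes for MRC against PBS, 6212 for MRC+L against PBS, 5403 for the 3 groups and 4745 shared stayed within 1.5 times under RLE (5043 and 6218 for the first 2), upper quartile (5098 and 6219) and library size only (4995 and 6147) and under DESeq2 (5718 and 6740) and limma-voom (5075 and 6244). Fits of only the 2 groups compared, which were not run for the 3 groups, gave 3706, 4895 and, shared, 3466. Leaving out 1 library gave 3562 to 6962 genes for MRC against PBS, 4702 to 7659 for MRC+L against PBS, 4056 to 7524 for the 3 groups and 3437 to 6271 shared. The lowest counts were without MRC replicate 1, MRC+L replicate 2, PBS replicate 1 and MRC replicate 1, and the highest without PBS replicate 2. A test against a 1.5-fold change gave 1640, 2293 and, shared, 1535 genes, and a threshold of 0.01 gave 3133, 3951, 3447 for the 3 groups and 2932 shared; a stricter rule lowers a count by construction. Limma-voom with quality weights for each library gave 8851, 9856, 10020 and 8200, with weights of 7.30 for PBS replicate 1 and 0.0784 for PBS replicate 2, so the comparison rested largely on 1 control library. With a replicate block the counts were 4283, 5490, 4426 and 4041, and 20, 22 and 12 lists were called.

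For MRC+L against MRC in the fit of 9 libraries, where 0 genes were called by edgeR (573 at an unadjusted p under 0.05), no low-count filter gave 15, DESeq2 25, only the 2 groups compared 654, limma-voom with quality weights 262 and limma-voom with group weights 79. Removing the length trend gave 4 (Id1, Dnajb1, Dnaja4 and Hspa1a), removing it with a replicate block 4 (Id1, Id3, Dnaja4 and Hspa1a), and removing the GC trend 4 (Dnajb1, Dnaja4, Hspa1a and Ifit1). Leaving out 1 library gave 0 to 89, with 89 without PBS replicate 2, 2 without PBS replicate 1 and 1 without PBS replicate 3. The fit of 6 libraries gave 654, and 137 to 1015 without 1 library, 5 against a 1.5-fold change (Id1, Id3, Dnaja4, Hspa1b and Hspa1a), 154 at a threshold of 0.01, 720 with a replicate block, 432 with the length trend removed and 357 with the trend removed and a block. Higher genes were 406 of the 654, but lower genes led with the trend removed (205 higher and 227 lower) and with a block as well (173 and 184); the cause was not tested. The genes named for small counts were chosen after their values were seen.

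With an estimated correlation 12 lists were called for MRC against PBS, 10 for MRC+L against PBS and 0 for MRC+L against MRC (of 12), also 0 in the fit of 6 libraries, and fry called 2 for MRC+L against MRC. Leaving out 1 library gave 19 to 22, 21 to 24 and 9 to 13 lists, and removing the length trend 20, 23 and 13. Cytosolic ribosomal proteins in MRC+L against PBS changed direction: the median was -0.175 with all libraries, and it ranged from -0.405 without PBS replicate 3 to 0.26 without PBS replicate 2. It was also positive, at 0.0553, with the length trend removed, which leaves the direction unsettled. For named genes, 3865 values kept direction and side of the threshold for MRC against PBS, 84 lost and 11 gained a call. For MRC+L against PBS the numbers were 3859, 61 and 11, and in the fit of 6 libraries 1871, 367 and 15.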

Other observations

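The families below and the tests of the scaling factors, of Ifnb1, and of the length trend, single PBS libraries and weights per group for the comparison of MRC+L with MRC, with their bounds, were chosen only after the result was seen, and so was the widening of the SEs below for the correlation between members. The SEs of list medians come from resampled list members and do not measure the spread between libraries. Genes were grouped into 185 families by the stem of their symbol. Guanylate-binding proteins (Gbp), interferon-induced defence genes, fell in 9 of 10 members in MRC against PBS (median -2.36, camera adjusted p = 2.01e-14, 0.277 with an estimated correlation) and in 10 of 10 in MRC+L against PBS. Matrix metalloproteinases (Mmp) fell in 7 and rose in 1 of 10 after MRC (median -0.78, adjusted p = 0.00227, 0.277 with an estimated correlation), with 2 higher without PBS replicate 3. Of 325 zinc finger genes (Zfp) 101 rose and 15 fell after MRC (median 0.27, adjusted p = 0.00732, 0.965 with an estimated correlation), and 115 rose and 24 fell after MRC+L, with 13 lower without MRC+L replicate 2, 14 without PBS replicate 1 and 15 without MRC+L replicate 3. The number that rose after MRC was 56 without MRC replicate 1 and 130 without PBS replicate 3, and 35 fell without PBS replicate 2 and 24 with the length trend removed. Zbtb genes, a related family of transcription factors, rose in 18 and fell in 2 of 38 after MRC (median 0.52, adjusted p = 0.00634, 0.965 with an estimated correlation), with 6 lower without PBS replicate 2. Sec genes of protein secretion rose in 11 of 25 after MRC with none lower (median 0.40, adjusted p = 0.0284, 0.352 with an estimated correlation), with 17 higher and 1 lower without PBS replicate 2, 1 lower with the length trend removed, and 6 or 7 higher without PBS replicate 1, MRC replicate 1 or MRC replicate 3.

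Interferon-stimulated genes such as Oas2 and Irf7 were lower after MRC, with a median of -2.43 over 47 genes. A trend with gene length and a single PBS library were each excluded as the whole cause: the median was -2.39 (SE 0.679) with the length trend removed and -2.34 (SE 0.581) without PBS replicate 2, the highest without 1 PBS library, or -2.32 there over the 47 genes tested with all libraries. The scaling factors lay between 0.970 and 1.02, a span of 0.0747 on the log2 scale, and the median would need a shift of 1.43 to reach -1. Applying these factors was therefore not the whole cause. Factors near 1 cannot show that the scaling itself was right, so a shift from composition was not tested. The span was the third reading of the factors, and by the first they were excluded and by the second left open. Less interferon beta transcript in exposed cells is a candidate source, but it stays open because counts of Ifnb1 were too few, with a mean of 8.67 in PBS and 2 in exposed libraries (one-sided exact permutation p = 0.0119, the smallest that 84 groupings can give). A higher interferon state of the PBS cultures, rather than a lower one of exposed cultures, cannot be told apart with 1 set of controls.

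The lack of calls between MRC+L and MRC with all 9 libraries was set against 3 causes. With the length trend removed the fit of 9 libraries called 4 genes, and at most 3 without 1 MRC or MRC+L library. The fit of 6 libraries with the trend removed called 106 to 600 over the same omissions. The trend, as far as the smooth correction removed it, was thus excluded as the whole cause. The spread of the 9 libraries was still 0.134 after that correction, and what the correction may have left was not tested. At most 89 genes were called with 1 PBS library left out, and 21 to 68 when 1 MRC or MRC+L library was left out together with PBS replicate 2, against 137 to 1015 in the fit of 6 libraries, so a single PBS library was excluded as the whole cause but not as a part of it, since the spread was 0.172 with all libraries, 0.0823 without PBS replicate 2 and 0.0707 in the fit of 6 libraries. These ranges were the third bound tried for both: a bound of 327 genes, 1 in 2 of the 654, excluded both, and the 79 genes called with 1 weight per group excluded the length trend and left the single library open. A wider spread of the PBS libraries, which enters the shared estimate, may be the cause. Fold changes of the 654 genes differed by at most 0.0192 between the 2 fits, while the median SE was 0.185 with 9 libraries and 0.0952 with 6. A larger error, and not a smaller change, thus went with the lack of calls. How much of that error comes from the PBS spread stays open. Limma-voom called 262 genes with quality weights, over the 100 that were set before as a sign of a wider PBS spread. These weights largely removed PBS replicate 2 (weight 0.0784), and with 1 weight per group 79 genes were called.

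Nuclear-encoded genes of the respiratory chain were lower in MRC+L than in PBS, with a median of -0.72, but the list was not called with an estimated correlation (adjusted p = 0.543), since its members moved together (correlation 0.828). With the length trend removed the median was -0.538 (SE 0.218), and without PBS replicate 2 it was -0.446 (SE 0.307). Both explanations stay open, since neither value lay below the bound of -0.4 by more than its SE, which is over list members and not libraries. With members taken as independent the first SE was 0.0423 and the length trend would have been excluded.

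Other splits of the libraries were too few to test chance for the pairs of groups, since 10 splits cannot give a share under 0.1. With all 9 libraries in the fit and the 6 compared ones divided anew, the real split gave 5050 genes for MRC against PBS and 6212 for MRC+L against PBS, and the fit of 6 libraries gave 654 for MRC+L against MRC. Each was the only 1 of 10 splits with as many, and the highest other split gave 0 genes by edgeR in each. In the fit of 9 libraries MRC+L against MRC gave 0 genes in the real split, which 10 of 10 splits equalled, with 0 as the highest other. For the 3 groups, 1 of 100 splits, drawn from 280, gave as many as the real 5403. A random division of all the libraries was excluded at that share. The highest other split gave 5006 and kept the PBS libraries together, which points to PBS against the rest as the main structure. The exclusion therefore does not cover the division of MRC from MRC+L.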
